A study of Mus musculus with 2 samples.

How the data were processed

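DNase-seq of cerebellum from 10-day-old female B6CASTF1/J mice was deposited as 2 libraries, biological replicates 1 and 2 of 1 group, with 1 technical replicate each. Both labels carry the same donor identifier and each names 3 females, so whether the replicates come from separate animals was not given in the sources used here. For replicate 2 the labels name 2 sequencing instruments, and for replicate 1 none. The nuclei were prepared by a protocol that the labels only point to.

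Per the file headers of the deposit's read-me, all files are in mm10 coordinates. Each library was called on its own, without pooling. The aligner, the peak caller, the footprint caller, their versions and the read totals were not given in the sources used here. The authors deposited 2 narrowPeak lists per library. The longer was taken as the main list and the shorter as the alternative, a choice made after the lists had been seen. Of the shorter lists 98.4% and 98.9% of peaks overlapped the longer list of the same library. In the authors' peak lists, column 7 is a signal per peak that is never negative, and the sources used here do not define it. Values below 1 were whole multiples of a library-specific step within a tolerance of 0.05 steps in 100% of cases (129476 and 264046 values), which points to a count scaled by a constant. Signal was used to rank, filter and describe peaks within a library; values of the 2 libraries stand side by side without a common scale. Log2 ratios of replicate 2 to replicate 1 signal are given in the closing section alone. They were compared between genes or peaks of the same pair of libraries, where a constant scale factor drops out. A change of the ratio with signal level drops out only where random lists or peaks were matched on signal. Random lists so matched had a median log2 ratio of 0.38 for the vascular and meningeal list and 0.85 for the housekeeping list. The authors' cleavage rate files give a false discovery rate (a q-value) per run of bases, and every listed value was under 0.05. The authors' footprint lists hold intervals and a further column, which in replicate 1, where it was counted, had the same value, 0.01, on each line. This other column therefore ranked nothing there, and only the intervals were used for both libraries, as deposited.

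Depth was not stated, so no limit of detection could be given. The step ratio of 2.16 and the peak ratios of 1.85 (longer lists) and 1.83 (shorter lists) describe how unlike the libraries were. Intervals on shares are exact (Clopper-Pearson) binomial 95% intervals and cover counting error only. With n = 2, mean ± SD (SD of the 2 libraries) is given for summary values and both values otherwise. No p-value was computed, since genes and peaks of a library are not replicates.

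Peaks were compared by overlap of at least 1 bp, beside 100 circular shifts within chromosomes. Peaks were classed by their middle base as promoter (within 500 bp of a transcription start), exon, intron or intergenic, in that order, with the GENCODE M21 basic annotation on the GRCm38 assembly, which shares its coordinates with mm10. A gene's peaks were those overlapping its body and 10 kb on each side, and its promoter signal was the highest signal of a peak overlapping 500 bp around any of its transcription starts, or 0 without one. A promoter peak can therefore count for neighbouring genes, and a peak that ends at the edge of the window can count in only one library. Some listed peaks of a library overlap or lie inside one another, and each was counted. A peak number is thus not a number of separate sites.

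Gene lists were fixed before the data were examined: 23 lists with 384 entries and 368 different genes. They cover granule cell precursors and the cell cycle, differentiating and mature granule cells, Purkinje cells, GABAergic interneurons, unipolar brush cells, Bergmann glia and astrocytes, oligodendrocytes, microglia, vascular and meningeal cells, erythroid cells, choroid plexus and ependyma, forebrain and midbrain-hindbrain patterning, posterior Hox genes, hepatocytes, skeletal muscle, germline, housekeeping, Sonic hedgehog signalling, activity-dependent genes, glutamate and GABA receptors, imprinting, and X inactivation. Ahsp was not found in the annotation. A list's median over its protein-coding members was placed among 10000 random lists of the same size drawn from 21938 protein-coding genes, matched on decile of gene span for peak numbers and unmatched for promoter signal. A percentile describes a library and is not a p-value. The rule for named genes, also fixed beforehand, took from each list the 3 members with most peaks and the 3 with the highest promoter signal (means of both libraries). To these it added up to 4 members without a promoter peak for the cerebellum's own cell types and up to 4 with a promoter peak in both libraries for other tissues. Genome-wide it took the 10 genes with most peaks, the 10 with the highest promoter signal, and 5 per direction with the largest difference in rank of promoter signal. Which lists count as the cerebellum's own was written down after the data had been seen. Genes named outside the rule were Atoh1, Gad1, Slc32a1, Mid1, and those of the distal sites, the Pax6 map and the 50 kb windows with unlike peak numbers, all picked after their values were seen. Kdm5d, Uty, Ddx3y and Eif2s3y were named in a test set down before its result was seen. Some genes that the rule or these searches took are not reported here.

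Motif content was the share of footprints, extended by 10 bp on each side, that held a consensus on either strand, divided by the share of windows of the same width 200 bp to each side, for 25 consensus sequences fixed beforehand. Shared footprints were compared with shifts along chromosomes and with shifts within peaks. Y chromosome peaks were matched to the rest of the genome with minimap2 2.31, and a match needed 90% identity over 80% of the peak.

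Alternatives fixed beforehand were a reciprocal overlap of 50%, equal numbers of top-ranked peaks, the strongest 50000 peaks, the shorter peak list, autosomes alone, 1000 bp promoters, starts of protein-coding genes alone, gene bodies alone or with 50 kb on each side, unmatched random lists, other motif backgrounds, and each library alone. Alternatives added after the data were seen were the strongest peak outside promoters, motif ratios divided by those of the reversed consensus, footprints inside the shorter list, and the shorter list for peak number, gene lists and cleavage rate. The percentile bounds of 97.5 and 2.5 and the motif ratio of 1.5 used to count results were also set after the data were seen.

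The steps were tested on simulated data. Of 10000 simulated peaks, 70% were given a partner and 70% were found to have one. Of simulated unchanged lists of long genes, 3% reached the 97.5th percentile when matched on span, and 93.5% when not matched, over 20000 genes. Lists with a doubled rate reached it in 100% of cases. A motif planted in 15% of 20000 windows was found in 15.0%. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0 and pyarrow 21.0.0, and figures matplotlib 3.10.9.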

Results

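Open chromatin was mapped in the cerebellum of 10-day-old female mice by DNase-seq, in which DNase I cleaves nuclear DNA where nucleosomes and other proteins leave it exposed. The animals were B6CASTF1/J mice, the F1 offspring of a cross between the laboratory strain C57BL/6J and the wild-derived strain CAST/EiJ. The design held 1 group of 2 biological replicates, each labelled as tissue of 3 females, and both labels carried the same donor identifier. There was no second tissue, age, sex or treatment, so the comparisons were between the replicates and between classes of genes or regions within each library. For each library there were peak lists, footprint lists and false discovery rates of the local cleavage rate. Replicate 1 had 188256 peaks, with a median width of 180 bp and 37.2 Mb covered (1.37% of the chromosomes). Replicate 2 had 347999 peaks, with a median width of 177 bp and 61.5 Mb covered (2.26%). Read totals were not part of the files used here. The authors' signal per peak rose in whole steps of 0.00576 in replicate 1 and 0.00267 in replicate 2, a ratio of 2.16. As peak numbers differed by 1.85 times between the libraries, each value is given for both in the order replicate 1, replicate 2, and no p-value was computed from genes or peaks of a library.

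Genes of the granule cell lineage lay in dense open chromatin in both libraries. Granule cells are the small glutamatergic neurons of the cerebellar cortex, and their precursors divide in the external granular layer after birth. The list of 21 genes of differentiating and mature granule cells had a median of 26 and 37 peaks over the gene body and 10 kb on each side. Random lists matched on gene span had 7 and 12, which put the list at percentile 100 in both libraries. The list of 20 genes of granule cell precursors and the cell cycle had 13.5 and 23 peaks against 5.5 and 9.5, again at percentile 100 in both. Every gene of these lists had a promoter peak in both libraries.

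Among the differentiating granule cell genes, Rbfox3, which encodes the neuronal splicing factor NeuN, held 105 and 255 peaks. Nfib held 103 and 170 and Nfix 84 and 132. Both encode nuclear factor I proteins, which act in granule cell maturation. The strongest promoter peaks of the list were those of Tiam1, an activator of the GTPase Rac (signal 11.9 and 23.7), Cbln1, a synaptic organiser that granule cells release (9.30 and 20.5), and Neurod1, a basic helix-loop-helix factor of differentiating granule cells (7.28 and 17.3). Of the precursor genes, Pax6 held 56 and 70 peaks, Meis1 48 and 70 and Gli2, a transcription factor of hedgehog signalling, 44 and 77. Cdk1, the kinase that drives mitosis, had a promoter signal of 6.62 and 12.4. Mcm2, a subunit of the replicative helicase, had 6.89 and 11.1, and Pcna, the sliding clamp of DNA replication, 5.63 and 12.7. Atoh1, which specifies the granule lineage, had 8 and 11 peaks and a promoter signal of 1.52 and 3.42.

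Purkinje cell and interneuron genes also carried more peaks than random lists of the same gene spans. Purkinje cells are the GABAergic output neurons of the cerebellar cortex, and their 20 genes had medians of 15 and 28 peaks against 8.5 and 14.5 (percentiles 99.7 and 99.9). Rora, which encodes a nuclear receptor required for Purkinje cell maturation, held 97 and 156 peaks. Ebf1 held 53 and 93. Itpr1, the inositol trisphosphate receptor of the calcium store, had a promoter signal of 6.82 and 16.5, the LIM homeobox gene Lhx1 6.81 and 14.99, and Ebf1 5.83 and 12.5. Pcp2, a classical Purkinje cell marker, had no promoter peak in either library, although 4 and 5 peaks lay around it. With the strongest 50000 peaks of each library the list's mean percentile was 74.3, and with the shorter peak list 91.9.

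The 15 tested genes of cerebellar GABAergic interneurons had medians of 13 and 23 peaks against 7 and 12 (percentiles 99.4 and 99.7), and all 15 had a promoter peak in both libraries. Their median promoter signal of 1.05 and 1.10, however, lay at percentiles 31.8 and 25.6 of random lists. Sorcs3 held 40 and 90 peaks, the cadherin gene Cdh22 26 and 53, and Pax2, an early marker of the interneuron lineage, 23 and 35. The receptor tyrosine kinase gene Kit had a promoter signal of 2.34 and 5.41 and the parvalbumin gene Pvalb 2.76 and 3.83. The long non-coding RNA gene Lhx1os, which was not part of the tested set of coding genes, shared its promoter peak with Lhx1. The list's mean percentile was 41.1 with the strongest 50000 peaks and 85.9 with 50 kb on each side of the gene. Unipolar brush cells are excitatory interneurons of the granular layer. Their 8 genes had medians of 15 and 24.5 peaks against 8.5 and 14 (percentiles 96.2 and 95.6). Plcb4 held 42 and 78 peaks and Lmx1a 20 and 41. Calb2, which encodes calretinin, had a promoter signal of 6.42 and 7.65 and Eomes 2.40 and 2.97, while Sln had no promoter peak in either library.

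Genes of Bergmann glia and astrocytes lay above random lists in both libraries, and those of oligodendrocytes did so in replicate 2. Bergmann glia are the radial astrocytes of the cerebellar cortex. The 19 genes of Bergmann glia and astrocytes had medians of 9 and 13 peaks against 5 and 8 (percentiles 99.4 and 98.6). Their mean percentile was 94.97 with 50 kb on each side and 96.02 among unmatched random lists. Slc1a2 and Slc1a3, the astrocytic glutamate transporter genes, held 20 and 44, and 15 and 28 peaks, and the folate enzyme gene Aldh1l1 held 19 and 35. The promoter signal of Fabp7, a radial glia fatty acid binding protein, was 6.28 and 14.1, that of the intermediate filament gene Vim 4.12 and 6.31, and that of Sox9 3.10 and 9.50. The 15 oligodendrocyte lineage genes had medians of 7 and 14 peaks against 5 and 8, at percentiles 91.6 and 99.5. Pdgfra, the receptor of oligodendrocyte progenitors, held 27 and 30 peaks, Mbp, which encodes myelin basic protein, 24 and 53, and Nkx2-2 12 and 31. Promoter signal was highest at Sox8 (1.93 and 4.35), Olig1 (1.93 and 3.69) and Myrf (2.31 and 3.13). The myelin gene Mobp had no promoter peak in either library.

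Genes of microglia, of vascular and meningeal cells, of erythroid cells and of choroid plexus and ependyma lay within the range of random lists by peak number. The 14 microglial genes had medians of 5 and 9 peaks against 5.5 and 8.5 (percentiles 42.3 and 55.4), and 4 of them had a promoter peak in both libraries. Cx3cr1, the fractalkine receptor gene, held 32 and 57 peaks without a promoter peak, Spi1 18 and 19, and Ptprc, which encodes CD45, 5 and 12. Irf8 had a promoter signal of 3.71 and 5.90 and Tmem119 0.755 and 2.14. The 16 vascular and meningeal genes lay at percentiles 59.6 and 48.1. Of these, the endothelial receptor genes Flt1 and Kdr held 19 and 36, and 6 and 14 peaks, with promoter signals of 1.48 and 1.57, and 1.27 and 1.89. The endothelial adhesion gene Pecam1 held 19 and 28 peaks, and Foxc1 13 and 15 with a promoter signal of 1.18 and 1.87. The 10 erythroid genes found in the annotation had medians of 2 and 3.5 peaks against 3.5 and 6 (percentiles 15.04 and 12.6). Klf1 and Slc4a1 each held 8 and 11 peaks. The promoter peak of Epb42 was seen in replicate 2 alone (signal 0.2001). The 10 choroid plexus and ependymal genes lay at percentiles 32.6 and 84.0. Foxj1, the regulator of motile cilia, had a promoter signal of 6.97 and 11.4 there, Otx2 1.11 and 1.61, the aquaporin gene Aqp1 0.847 and 1.64, and Kl 0.623 and 0.891. Otx2 held 16 and 29 peaks, Clic6 8 and 15, and Kcne2 10 and 12.

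**Figure D1:**
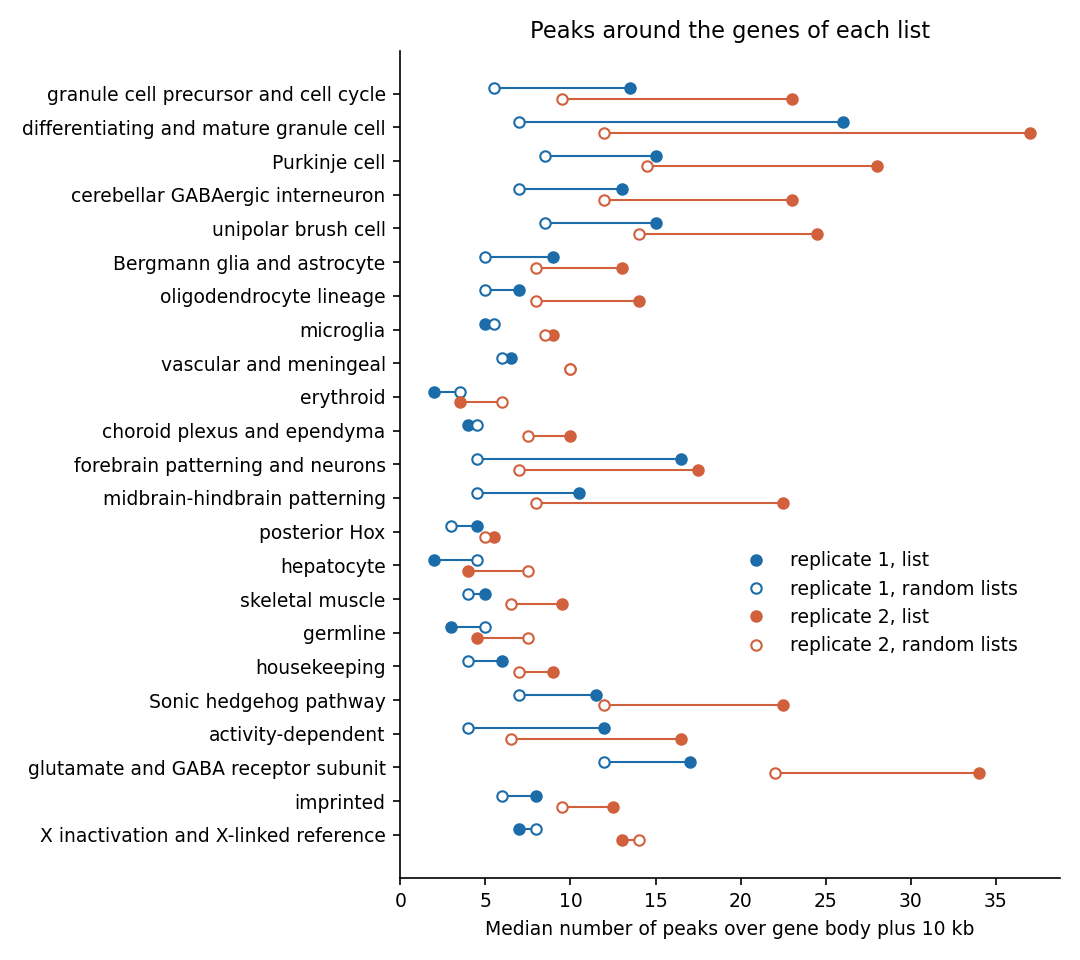
Median number of peaks over the gene body plus 10 kb for each of the 23 gene lists (filled circles) and the median over 10000 random lists matched on gene span (open circles), in replicate 1 (blue) and replicate 2 (orange). Differentiating granule cell genes had 26 and 37 peaks against 7 and 12, and hepatocyte genes 2 and 4 against 4.5 and 7.5.

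Genes of tissues outside the brain served as a background. The 18 hepatocyte genes had medians of 2 and 4 peaks against 4.5 and 7.5 (percentiles 1.52 and 1.94), and their promoters carried a peak in 1 and 4 cases. Apoa1, an apolipoprotein gene, was the 1 with a promoter peak in both (0.380 and 0.371). Apoh held 12 and 19 peaks and Hnf4a 6 and 14, none of which lay at the gene's own promoter. Tat and Apob had a promoter peak in replicate 2 alone (0.365 and 0.256). Germline genes had 3 and 4.5 peaks against 5 and 7.5 (percentiles 8.51 and 3.71). Dazl, which encodes a germ cell RNA-binding protein, nevertheless had a promoter signal of 6.07 and 13.8, and Dmc1, the meiotic recombinase gene, 1.28 and 1.504. Ddx4 held 6 and 8 peaks without a promoter peak. A promoter peak of signal 0.296 in replicate 2 was counted for both protamine genes, Prm1 and Prm2, which lie side by side and held 5 and 6, and 5 and 10 peaks. Skeletal muscle genes lay at percentiles 74.9 and 92.8. Mylpf, a myosin light chain gene, had a promoter signal of 8.97 and 14.8, Mybpc2 0.790 and 0.635, Myod1 0.565 and 0.918, and Ryr1, with 25 and 41 peaks, 0.300 and 0.619. Casq1 held 15 and 19 peaks, and Acta1 5 and 19. The hepatocyte list no longer lay under the 2.5th percentile when 50 kb on each side was counted (mean percentile 38.1) or when only the strongest 50000 peaks were used (19.04).

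Regional patterning genes of the brain carried more peaks than random lists. The 18 forebrain genes had medians of 16.5 and 17.5 peaks against 4.5 and 7 (percentile 100 in both), but their median promoter signal of 1.03 and 0.807 lay at percentiles 27.9 and 15.3 of random lists. With the strongest 50000 peaks the list fell to a mean percentile of 23.8. The homeobox genes Dlx1 and Dlx2 held 24 and 34, and 22 and 29 peaks. Neurod6 had a promoter signal of 2.71 and 5.05, the LIM homeobox gene Lhx2 2.13 and 4.33, Bcl11b 2.34 and 3.13, and Dlx6 1.37 and 2.48. The 18 genes of midbrain and hindbrain patterning had 10.5 and 22.5 peaks against 4.5 and 8 (percentile 100 in both), but a mean percentile of 60.9 with the strongest 50000 peaks. En2 and En1, the engrailed genes that pattern the midbrain and cerebellar primordium, had promoter signals of 6.63 and 14.8, and 3.75 and 8.78. Egr2 had 4.85 and 8.25 and Pax3 1.62 and 3.11. Pax5 held 43 and 70 peaks, Pax3 27 and 55, and Lmx1b 28 and 44. The 18 posterior Hox genes lay at percentiles 89.3 and 66.6, with a promoter peak in both libraries at 3 of them. These were Hoxa10 (1.79 and 1.81), Hoxc10 (1.19 and 1.68) and Hoxd9 (0.917 and 0.758). Hoxd8 held 9 and 21 peaks, Hoxd13 12 and 15, and Hoxa9 13 and 12.

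Genes of hedgehog signalling and of neuronal activity carried more peaks than random lists. The 16 Sonic hedgehog pathway genes, 7 of which were also in the precursor list, had 11.5 and 22.5 peaks against 7 and 12 (percentiles 97.9 and 99.7). Sonic hedgehog from Purkinje cells is the main mitogen of granule cell precursors. Gli2 led by peak number, the co-receptor gene Boc held 30 and 70 and the inhibitor gene Sufu 28 and 51. Sufu also had the strongest promoter peak of the list (9.54 and 21.4), followed by Mycn (3.05 and 8.23) and Gli2 (3.67 and 6.58). With the shorter peak list the pathway's mean percentile was 94.6. The 18 activity-dependent genes, which respond to neuronal firing, had 12 and 16.5 peaks against 4 and 6.5 (percentile 100 in both). Egr1 had a promoter signal of 13.0 and 22.0, Gadd45b 10.9 and 23.2 and Dusp1 10.5 and 20.2. Bdnf, a neurotrophin gene, held 11 and 24 peaks, Dusp1 18 and 19, and Gadd45b 12 and 23. The 21 glutamate and GABA receptor genes lay at percentiles 93.2 and 97.4. The NMDA receptor genes Grin2b and Grin2a held 60 and 95, and 41 and 87 peaks, and Grik2 36 and 72. Promoter signals in this list were 6.22 and 10.9 at Gria2 and 3.91 and 7.84 at Grik2.

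By promoter signal, housekeeping genes stood above the other lists. Their 15 promoters had medians of 7.24 and 14.3 against 1.80 and 2.67 in random lists (percentiles 99.8 and 99.9), led by Ppia (12.4 and 23.1), Rplp0 (11.4 and 21.6) and Ywhaz (10.2 and 20.3). Their peak number was ordinary, at percentiles 88.6 and 85.6, with 19 and 17 peaks at Gapdh, 11 and 17 at Polr2a, and 9 and 16 at Ywhaz. Granule cell genes had median promoter signals of 3.53 and 7.25 (percentiles 85.6 and 93.5) and precursor genes 3.42 and 6.997 (83.8 and 91.8). Other lists of the cerebellum's own cell types lay lower, with Purkinje cell genes at 68.4 and 55.95 and GABAergic interneuron genes at 31.8 and 25.6. Unipolar brush cell genes lay at 32.9 and 32.3, Bergmann glia genes at 30.1 and 38.2 and oligodendrocyte genes at 23.0 and 31.1. Midbrain and hindbrain patterning genes lay at 25.1 and 26.5, and forebrain genes at 27.9 and 15.3. Promoter signals of hepatocyte and germline genes had a median of 0 in both libraries, at percentiles 2.00 and 0.565, and 2.14 and 0.765. Microglial genes lay at percentiles 2.63 and 6.13, posterior Hox genes at 1.96 and 3.44, skeletal muscle genes at 2.15 and 3.68 and erythroid genes at 3.70 and 1.73. Signal was the authors' own value per peak, used here to rank promoters within a library, and its definition was not given in the sources used here.

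By the strongest peak outside promoters, a measure chosen after the peak numbers were seen, granule cell and activity-dependent genes lay above random lists, and several other neuronal lists lay closer to them than by peak number. Around differentiating granule cell genes its median signal was 5.83 and 12.5, against 1.71 and 2.68 in random lists (percentile 100 in both). Precursor genes had 4.48 and 7.88 against 1.35 and 2.08, and activity-dependent genes 4.50 and 7.84 against 0.885 and 1.25, both at percentile 100. Bergmann glia genes lay at percentiles 98.9 and 99.8 and oligodendrocyte genes at 98.3 and 99.0. Purkinje cell genes lay at 82.3 and 79.2, GABAergic interneuron genes at 82.9 and 90.7 and forebrain genes at 89.8 and 93.5. Midbrain and hindbrain patterning genes had a mean percentile of 88.3. Posterior Hox genes lay at 98.1 and 98.3 and imprinted genes at 98.6 and 99.5.

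Several of these distal sites, picked after their values were seen, were mapped to base positions in the mm10 build. A motif counted as inside a footprint if it fitted the footprint extended by 10 bp on each side. It could thus lie partly or wholly beside the footprint itself. Other consensus sites, SP/KLF at Ptch1 and Zic1 and EBF and T-box at Slc17a7, also counted as inside in both libraries. No background rate was set beside these single sites. In an intron of Ptch1, the hedgehog receptor gene, a peak at chr13:63552601-63552780 in replicate 1 had a signal of 8.23, and the peak at chr13:63552621-63552780 in replicate 2 had 17.0. It held the E-box CCATCTGT at chr13:63552722-63552729, of the kind bound by ATOH1 and NEUROD1, inside a footprint in both libraries. Near Boc, outside its gene body and in an intron of another annotated gene, a peak starting at chr16:44479961 had a signal of 7.61 and 16.3. It held the E-box CCATCTGC at chr16:44480065-44480072, again inside a footprint in both. The peak between genes near Zic1, at chr9:91355741-91355960, had 8.19 and 16.9 and held an NRF1 site, GCGCATGCGC, at chr9:91355916-91355925 in footprints of both. Beside Slc17a7, which encodes a vesicular glutamate transporter, an intergenic peak at chr7:45162281-45162440 had 14.4 and, with its start at 45162241, 22.0 in replicate 2. It held the CTCF site CCACCAGGTGGC at chr7:45162378-45162389 in footprints of both libraries, while an E-box at chr7:45162306-45162313 lay outside the footprints. Intronic peaks of Nfib starting at chr4:82513221 (10.4) and chr4:82513201 (21.1), and of Nfia at chr4:97868941-97869140 (11.2 and 19.4), held an SP/KLF site and the NFY site AGCCAATCA, each inside footprints of both libraries.

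Pax6 showed how such peaks were spread over a gene and the 10 kb on each side. Pax6 encodes a paired-box factor of granule cell precursors and lies on the plus strand at chr2:105668900-105697364. In the window from 105658900 to 105707364, 56 and 70 peaks were called. Most lay in introns of any annotated gene, 35 and 44, while 11 and 15 lay in exons, 9 and 8 at promoters and 1 and 3 between genes. The strongest was the promoter peak at chr2:105668721-105668920 in replicate 1 (5.68) and chr2:105668721-105668880 in replicate 2 (12.04). The window also covers the annotated ends of Pax6os1, Paupar and Elp4, whose exons, introns and starts count in these classes. Intron and exon peaks before the Pax6 start thus lie in Pax6os1 or Paupar, and those beyond its end in Elp4.

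**Figure D2:**
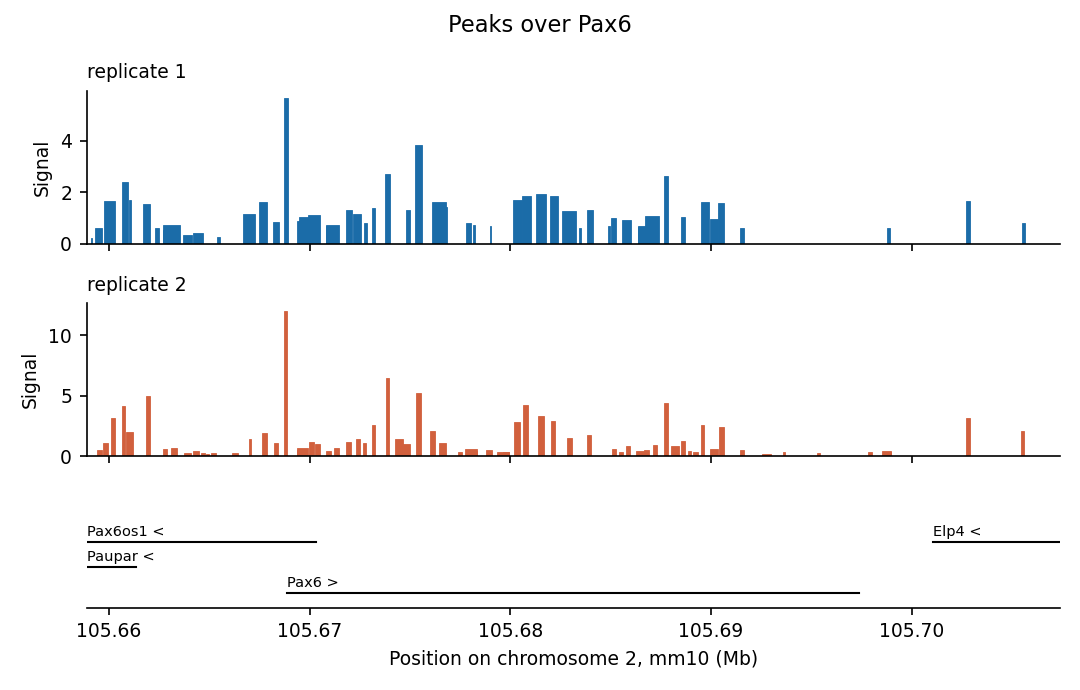
Peaks over Pax6 and 10 kb on each side on chromosome 2 of mm10, drawn to scale by position (Mb) with the authors' signal per peak as height, for replicate 1 (top, blue) and replicate 2 (middle, orange) on separate vertical axes, above the annotated genes with their strand. The tallest bar in both libraries is the promoter peak, with 5.68 and 12.04.

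Promoters held a larger share of the peaks than chance placement gave. A promoter was within 500 bp of an annotated transcription start, and 27173 peaks of replicate 1 and 33378 of replicate 2 lay there, 14.4% (95% interval 14.3 to 14.6) and 9.59% (9.49 to 9.69), with a mean of 12.01% ± 3.42 (SD, n = 2). Peaks shifted at random along their chromosomes fell there in 2.28% of cases. Exons held 7.202% ± 0.124 against 3.30%, introns 44.8% ± 1.91 against 42.1%, and intergenic sequence 36.0% ± 1.64 against 52.3%. Of the 10000 strongest peaks, 67.1% and 67.5% lay at promoters, and promoters held 36.7% and 35.2% of the summed signal. Of 21938 protein-coding genes, 14739 (67.2%) and 15816 (72.1%) had a promoter peak, 14687 in both, 52 in replicate 1 alone and 1129 in replicate 2 alone. The difference in promoter share between the libraries went with the number of weak peaks: beyond rank 100000, 5.90% and 5.02% were promoter peaks.

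The strongest promoter in both libraries was that of Dynlt1b, a dynein light chain gene, with signals of 36.8 and 70.3. It was followed by Hjurp, a chaperone of the centromeric histone (31.1 and 61.2), Nup107, a nuclear pore gene (29.6 and 55.6), and by the peak shared by Mplkip and Sugct (27.5 and 55.8). Bahcc1 (25.1 and 54.6), Eif4g3 (27.1 and 40.8), Fzr1 (20.7 and 45.2), Hivep3 (23.4 and 41.0) and Amd1 (21.4 and 42.6) completed the 10 strongest by mean. Most peaks were counted over Gm20388 (801 and 1550) and Fgfr2 (356 and 687), whose annotated spans reach over several other genes. Next came Gse1 with 139 and 297, the transcription factor gene Camta1 with 141 and 281 and the cell adhesion gene Lsamp with 128 and 273. Ntm (116 and 282), Asic2 (136 and 259), Nav2 (119 and 265), Gm37240 (137 and 246) and the splicing factor gene Rbfox1 (126 and 248) followed. Peaks among the 10 strongest also lay at sites of repeated sequence, such as the ribosomal RNA region at chr17:39846781-39846900 (33.1 in replicate 1) and the pseudogene 2610005L07Rik at chr8:20424741-20424920 (30.6 and 43.8).

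Footprints carried the binding motifs of architectural, granule cell and promoter factors. Footprints are short stretches protected from DNase I inside accessible sites, and 475985 and 1008184 were listed, with median widths of 11 and 12 bp. Of these, 87.0% and 84.2% lay in a peak. The motif of CTCF, the main insulator protein of mammalian genomes, was found in 6368 and 7844 footprints extended by 10 bp, 45.8 and 31.4 times as often as in windows 200 bp to the side. The full site of nuclear factor I was enriched 21.1 and 26.2 times, on 285 and 615 footprints. The ZIC motif, whose factors are abundant in granule cells, had ratios of 8.84 and 7.56. Its consensus can lie inside that of CTCF, and CTCF sites were not taken out. The RFX motif had 8.95 and 7.76 and the EBF motif 2.95 and 4.57. The E-box of ATOH1 and NEUROD factors was in 6378 and 14745 footprints, with ratios of 2.90 and 3.12. Sites of REST, a repressor of neuronal genes, had 4.33 and 11.1, on only 39 and 150 footprints. CREB sites had ratios of 4.04 and 3.35, the CAGCTG E-box 1.81 and 1.95 and the hedgehog effector motif GLI 1.34 and 1.77.

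Motifs of general promoter factors were enriched too, with ratios of 3.95 and 2.78 for NRF1, 3.17 and 2.80 for SP/KLF, 2.22 and 1.89 for YY1, 2.06 and 1.62 for ETS and 1.82 and 1.53 for NFY. These motifs concentrated at promoters: NRF1 sites were in 1.51% and 1.11% of promoter footprints and in 0.123% and 0.0660% of the others. Neurogenic E-boxes had the opposite distribution, with 0.330% and 0.396% of promoter footprints and 1.71% and 1.70% of the others, as did CTCF sites, with 0.270% and 0.214% against 1.73% and 0.903%. AP-1 (0.962 and 1.01), TEAD (0.941 and 0.940), HNF4 (0.897 and 0.924) and MEF2 motifs (0.911 and 0.841) were near or below the background. Several motifs were rarer in footprints than beside them, with ratios of 0.708 and 0.795 for ROR, 0.706 and 0.760 for T-box, 0.683 and 0.748 for SOX, 0.490 and 0.518 for LIM homeobox and 0.386 and 0.397 for GATA. HNF1 sites were seen in 0 and 1 footprints, too few for a ratio. Against windows inside peaks only, the mean ratios of ETS (0.649), NRF1 (0.842), YY1 (0.701) and NFY (0.805) fell below 1, those of SP/KLF and CREB fell to 1.001 and 1.21, those of the CAGCTG E-box, EBF and RFX to 1.39, 2.44 and 2.62, and that of LIM homeobox rose to 1.14. AP-1 (1.21), MEF2 (1.22), HNF4 (1.33), TEAD (1.53) and T-box motifs (1.07) were above 1 against these windows. CTCF, nuclear factor I, ZIC and the neurogenic E-box stayed above 1 in both libraries against those windows (14.3 and 7.05, 9.35 and 8.46, 5.14 and 3.26, 1.99 and 1.67). So did RFX (2.97 and 2.26), EBF (2.08 and 2.81), REST (1.85 and 6.78) and the CAGCTG E-box (1.47 and 1.32). The mean ratio of GLI was 1.33. The ZIC values include any ZIC sites that lie inside CTCF sites.

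**Figure D3:**
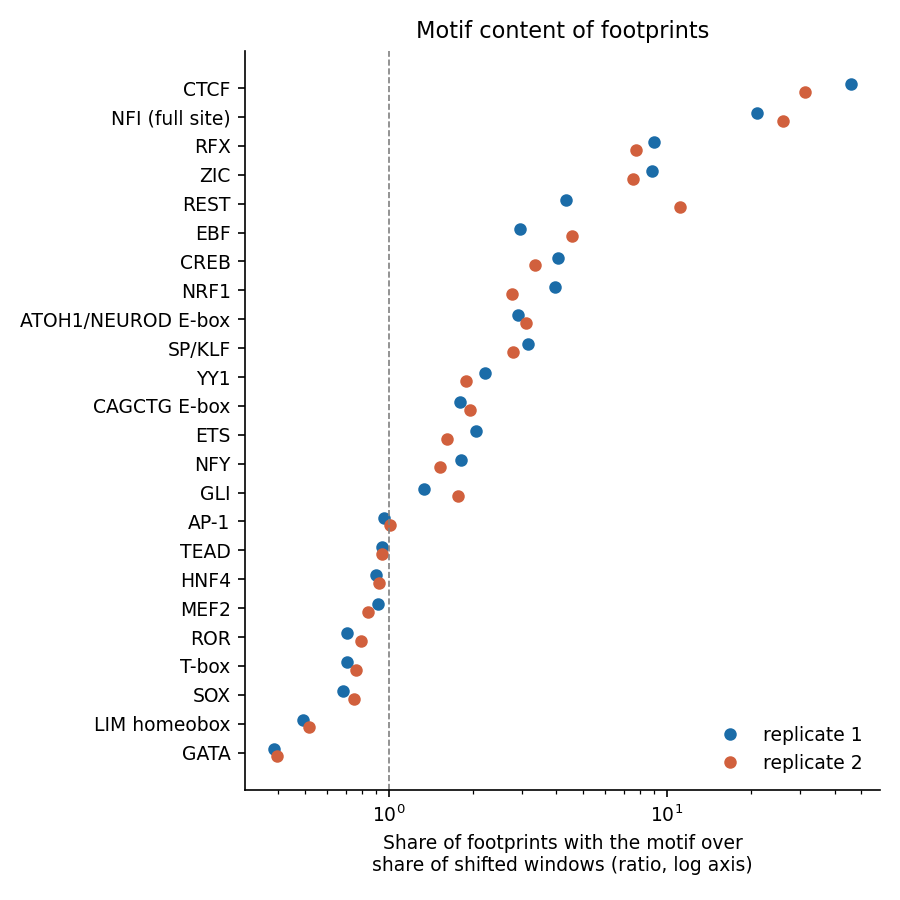
Ratio of the share of footprints holding each motif to the share of windows moved by 200 bp, on a log axis, in replicate 1 (blue) and replicate 2 (orange); the dashed line marks a ratio of 1. CTCF has the highest ratios, 45.8 and 31.4, and GATA the lowest, 0.386 and 0.397; HNF1 is left out for want of sites.

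The X chromosome had far fewer peaks than the autosomes. Cells of females silence most genes on an X chromosome. Peak density on the X was 29.3 and 54.5 per Mb, against a median over autosomes of 75.9 and 142 per Mb, a ratio of 0.385 ± 0.00167 (SD, n = 2). Promoter peaks on the X had a median signal 0.579 and 0.661 times that on the autosomes, and peaks outside promoters 0.565 and 0.522 times. Chromosome 11 was the densest, with 105 and 190 peaks per Mb. Counted per protein-coding gene the X to autosome ratio was 0.570, and with the strongest 50000 peaks it was 0.237. Alleles of the 2 parents could not be told apart in these lists.

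Kdm6a and Kdm5c, chromatin regulators that escape X inactivation in mice, had strong promoters. Kdm6a had a promoter signal of 18.6 and 36.7, Kdm5c 8.89 and 17.0, and Ftx, a long non-coding RNA gene of the X inactivation centre, 7.92 and 16.2. The 9 coding genes of the X list had median promoter signals of 6.91 and 10.3 (percentiles 98.2 and 94.2) and ordinary peak numbers (percentiles 31.9 and 42.8). Tsix held 15 and 22 peaks, Jpx 14 and 15 and Kdm6a 14 and 20. The 22 coding genes of the imprinted list, which are expressed mainly from the allele of a given parent, lay at percentiles 93.6 and 91.5 by peak number and 74.3 and 83.3 by promoter signal. Inpp5f had a promoter signal of 11.3 and 22.1, Ube3a 10.1 and 21.5 and the antisense gene Nespas 5.38 and 11.3. Gnas held 15 and 40 peaks, Igf2r 15 and 29, and Dlk1 0 and 43.

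**Figure D4:**
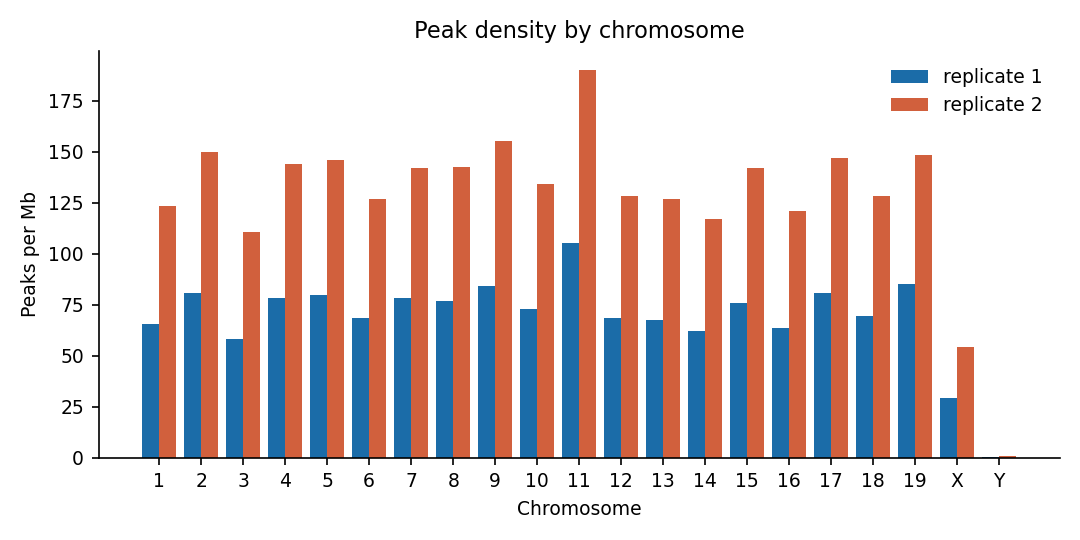
Peaks per Mb on each chromosome in replicate 1 (blue bars) and replicate 2 (orange bars). Chromosome 11 is the highest, with 105 and 190 peaks per Mb, the X stands at 29.3 and 54.5, and the Y is close to 0.

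Between the replicates, strong sites were shared and weak ones were found mainly in replicate 2. Of the peaks of replicate 1, 170558 (90.6%) overlapped a peak of replicate 2, against 5.00% after random shifts (4.79 to 5.23). In the other direction 171164 peaks of replicate 2 (49.2%) overlapped replicate 1, against 2.67% (2.57 to 2.81). Promoter peaks were shared in 94.0% and 76.6% of cases and intergenic peaks in 89.0% and 45.3%. In the weakest decile by signal 65.2% and 7.201% had a partner, and in the strongest decile 99.6% and 99.3%. Signal ranks of shared peaks correlated across peaks, with a Spearman coefficient of 0.931 for all and 0.979 for promoter peaks; peaks are not independent replicates. When the same number of top-ranked peaks was taken from each library, 76.1% had a partner in either direction. At 14687 promoters with a peak in both, the Spearman coefficient across genes was 0.98.

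**Figure D5:**
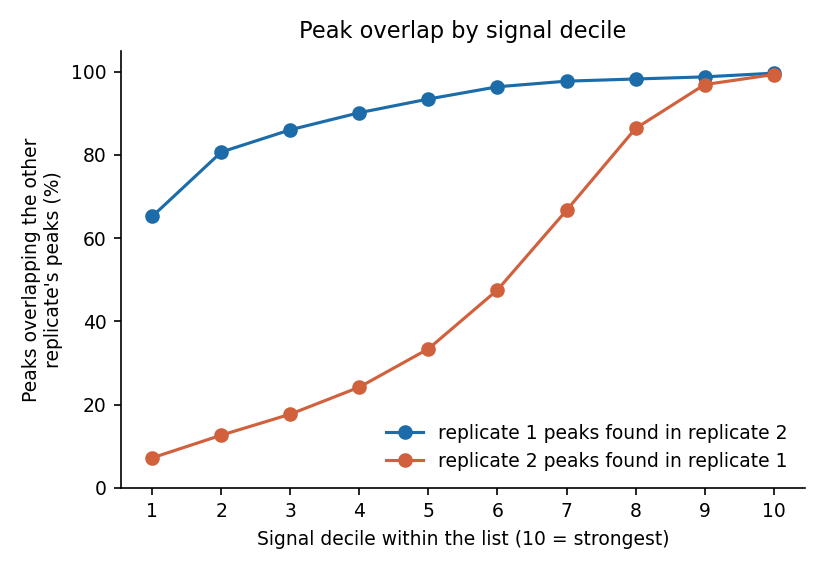
Share of peaks (%) that overlap a peak of the other library by at least 1 bp, by signal decile within each list (10 is the strongest), for replicate 1 peaks in replicate 2 (blue) and the reverse (orange). The shares rise from 65.2% and 7.201% to 99.6% and 99.3%.

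Some loci differed in the number of peaks far more than the libraries did. This search in windows of 50 kb was made after the gene lists had been seen. Of 48362 windows with a peak, 1935 held more peaks in replicate 1, the library with fewer peaks, by any margin. Only 14 windows held 10 or more extra peaks in replicate 1. The window from Hoxa3 to Hoxa11 at chr6:52200001-52250000 held 38 and 21, and the next, with Hoxa13, 15 and 4. Windows of other developmental transcription factor genes were Tbx15 with 25 and 10, Nkx2-3 with 29 and 19 and Dlx5 and Dlx6 with 27 and 17. In the opposite direction, the window of Dlk1, an imprinted gene, held 2 and 53 peaks, that of Hoxd3 to Hoxd9 4 and 57, and that of Timp2 and Lgals3bp 8 and 67. The replicate 2 peaks in the Dlk1 and Hoxd windows were weak, with median signals of 0.0880 and 0.208, against 0.379 in the whole list.

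By rank of promoter signal, Herc3 (2.30 and 8.99), Zfp68 (4.33 and 13.6), Aars, an alanyl-tRNA synthetase gene (5.57 and 17.0), Ppp1r11 (5.42 and 16.3) and Ivd (3.597 and 11.4) stood highest in replicate 2 relative to replicate 1. Gm10719, in a cluster of repeated sequence at the start of chromosome 9, had 20.99 and 0.990. Pik3ca (8.10 and 1.43), Pagr1b (8.41 and 1.94), Ganc (5.29 and 0.133) and Xntrpc (4.89 and 1.38) stood lower in replicate 2, but a strong peak of replicate 2 lay just beyond the promoter window at each of these 4 genes.

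Footprints, too, were shared mostly in the direction from replicate 1 to replicate 2. Those of replicate 1 overlapped those of replicate 2 in 77.3% of cases and the reverse in 33.4%, against 1.08% and 0.503% after shifts along the chromosome. Inside peaks shared by both libraries the shares were 79.3% and 50.95%, against 55.4% and 38.3% when footprints were shifted within their peak. Of the weakest decile of peaks 19.03% and 51.9% held a footprint. The listed bases with a false discovery rate of the cleavage rate under 0.05 summed to 62.5 and 103 Mb, and 57.9 Mb were common to both, 92.6% and 56.1% of each. Peaks of the longer list held 58.5% and 59.0% of those bases.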

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

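The tests of depth and of cell mix on the unshared peaks were chosen only after related values had been seen, and so was the rule that weighed forebrain tissue against lists with no tie to the forebrain. Peaks on the Y chromosome were singled out because the animals are labelled female: 54 were listed in replicate 1 and 103 in replicate 2. Promoters of Kdm5d, Uty, Ddx3y and Eif2s3y, which are broadly expressed in males, carried a promoter peak of at least 10% of their X-linked partner's signal in 0 of 4 cases, which argues against male tissue in the libraries. Over the gene bodies and 10 kb on each side, replicate 1 had 0 peaks at each gene. Replicate 2 had 3, 1, 1 and 1 there, none at a promoter of these genes. Sequence shared with the X or the autosomes is a candidate source: 58.8% of Y peaks (mean of 55.6% and 62.1%) matched a sequence elsewhere, against 44.4% and 32.04% of random Y windows. The share of Y peaks lay between the bounds set beforehand (80% and 20%), so this source cannot be told apart from others. Most Y signal, 88.9% and 85.3%, lay beyond 90 Mb, where the highest Y peaks (9.35 and 4.13) matched the X at 96.4% and 96.5% identity; peaks with a match held 62.5% and 55.1% of the Y signal, and the design gives no biological explanation to test.

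Of the peaks of replicate 2, 49.2% had a partner in replicate 1. Deeper sequencing of replicate 2 may account for this: 99.3% of its strongest decile had a partner and the missing partners were mostly those of weak peaks. The bound for this test was set after the data had been seen, and missing partners at weak peaks are not particular to depth. The test therefore cannot single depth out. A different mix of cell types in the dissections cannot be told apart from deeper sequencing at these numbers. Around the genes of each list, the share of strong replicate 2 peaks without a partner was at most 4.44%, which was 2 of 45 near midbrain-hindbrain patterning genes (exact 95% interval 0.543% to 15.1%), under the bound of 5% but with an interval that crosses it. The same share was 3 of 272 near granule cell genes and 2 of 95 near Purkinje cell genes.

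Over 16 genes, the median log2 ratio of forebrain patterning genes was 0.05 against 0.77 in random lists not matched on signal. The percentile was the lowest, with that of the GABAergic list, among 18 lists compared. Forebrain patterning genes thus had a lower promoter signal in replicate 2, relative to other genes. Signal level and GC content do not account for it: random lists matched on both had 0.50, and the list lay at percentile 0.03. Shared peaks outside promoters around these genes were also low, at -0.06 against 0.52 in peaks matched on signal (percentile 0 for more forebrain tissue in replicate 1) and 0.44 in peaks matched on signal and GC content (percentile 0 for GC content of the peaks outside promoters), so GC content leaves the difference in place. More forebrain tissue in replicate 1 may account for it, but 3 of 5 lists with no tie to the forebrain, among them midbrain-hindbrain (0.10) and erythroid genes (0.09), also lay under the 2.5th percentile outside promoters, as did 9 of all 22 lists compared, and peaks around a gene are not independent. What stays open is forebrain tissue and the cluster of peaks of replicate 1 at Dlx5 (22 and 10 peaks); the design names no biological difference between the libraries.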

How the results depend on the processing

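Alternatives chosen only after the data were seen were the shorter list for peak number, gene lists and cleavage rate, the strongest peak outside promoters, footprints inside the shorter list and the reversed consensus. A stricter footprint threshold and equal numbers of top-ranked footprints could not be run for both libraries, since the footprint list of replicate 1 holds no ranking value. The cause was not tested for any change below unless stated. With the shorter list the mean peak number fell from 268128 to 166042, which follows from its construction, and it ranged from 188256 to 347999 without each replicate. The share of replicate 1 peaks found in replicate 2, 90.6%, became 77.0% with reciprocal overlap, 76.1% with equal numbers, 87.6% with the strongest 50000, 94.1% with the shorter lists and 90.8% on autosomes. For replicate 2 in replicate 1, 49.2% became 41.6%, 76.1%, 87.5% and 51.6% in that order and 49.3% on autosomes. The Spearman coefficient of 0.931 was 0.937 with reciprocal overlap, and the Pearson coefficient of log2(signal + 1) was 0.964. The promoter share of 12.01% was 17.6% with 1000 bp, which widens the class, 31.7% for the strongest 50000 and 16.6% for the shorter lists, with a range of 9.59% to 14.4% without each replicate.

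Of 23 lists, 9 lay among the upper 2.5% of random lists by peak number in both libraries, 5 with 50 kb on each side and 3 (precursors, granule cells and activity-dependent genes) with the strongest 50000, and 9 to 10 without each replicate. With the strongest 50000, Bergmann glia and hedgehog genes had mean percentiles of 97.535 and 97.565 but were not in the upper 2.5% in both libraries. Further lists that left it were Purkinje cell genes with gene bodies alone (97.04), GABAergic genes with the shorter list (95.99), and forebrain (88.3) and hedgehog genes (88.7) with 50 kb. Unipolar brush cell (99.7) and receptor genes (100) entered it with unmatched random lists, and oligodendrocyte genes with gene bodies alone (97.58). The 1 list at the low end, hepatocyte, left it (0 lists) with gene bodies alone, with 50 kb, with the strongest 50000 and by the strongest peak outside promoters. List genes with a promoter peak in both libraries fell from 248 to 159 with the strongest 50000 and numbered 251 to 291 in each library alone. By promoter signal, the 1 list at the high end became 1 to 2 without each replicate. The 2 lists at the low end became 0 with the shorter list and 3 to 4 without each replicate. Across all lists and settings, 154 of 184 calls by peak number were unchanged, 23 were lost and 7 gained, and of 92 by promoter signal 86, 2 and 4.

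Footprints numbered 742084 on average, and 475985 to 1008184 without each replicate. Their overlap of 77.3% was 47.5% with reciprocal overlap and 78.0% inside the shorter lists, and that of 33.4% was 22.4% and 36.7%. Of 25 motifs, 14 had a ratio over 1.5 in both libraries, and 8 did against windows inside peaks. The X to autosome ratio of 0.385 was 0.570 per protein-coding gene and 0.237 for the strongest 50000. Peaks held 58.8% of bases with a low false discovery rate, and 37.5% in the shorter lists. Of the named genes' peak numbers 393 of 632 moved by 1 SD or more under the settings that keep both libraries, and of their promoter signals 55 of 474.

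Single motifs moved with the background chosen, and HNF1, which had no ratio in replicate 1, was left out. Against windows inside peaks, LIM homeobox rose from below 1 to 1.14, and ETS (0.649), NRF1 (0.842), YY1 (0.701) and NFY (0.805) fell below 1. CTCF was then at 10.7, nuclear factor I 8.91, RFX 2.62, CREB 1.21, the neurogenic E-box 1.83, the CAGCTG E-box 1.39, ZIC 4.20, EBF 2.44 and SP/KLF 1.001. AP-1 (1.21), MEF2 (1.22), HNF4 (1.33), TEAD (1.53) and T-box (1.07) also rose from below 1, and SOX was at 0.949, ROR 0.999 and GATA 0.9099. Without the 10 bp extension, which asks for the whole motif inside the footprint, CTCF was at 167, REST 24.5, nuclear factor I 74.05, RFX 35.4, CREB 9.05, the neurogenic E-box 3.85, the CAGCTG E-box 2.43 and ZIC 27.4. EBF was at 6.82, ETS 2.41, NRF1 11.3, SP/KLF 7.24, NFY 1.91 and GLI 2.15. MEF2 was at 0.422, AP-1 0.581, SOX 0.466, ROR 0.523, LIM homeobox 0.359, GATA 0.175, HNF4 0.839, TEAD 0.786 and T-box 0.496. With windows moved by 100 bp, CTCF was at 13.03, RFX 4.78, CREB 2.19, the neurogenic E-box 2.04, the CAGCTG E-box 1.4999, ZIC 6.101, ETS 1.202, NRF1 2.05, SP/KLF 2.26, YY1 1.57 and NFY 1.24. AP-1 was at 0.895, LIM homeobox 0.561, GATA 0.486, HNF4 0.944, TEAD 0.9497 and T-box 0.788. Outside promoters, CTCF was at 50.5, RFX 14.5, AP-1, which rose from below 1, 1.02, the neurogenic E-box 3.21, the CAGCTG E-box 2.07, ZIC 9.86 and ETS 1.24. There NRF1 was at 4.26, SP/KLF 3.25, YY1 2.31, GATA 0.401, TEAD 0.958 and T-box 0.775. Division by the ratio of the reversed consensus gave no value for REST and SP/KLF, and for RFX one in replicate 2 alone (3.88). By it LIM homeobox (1.06), MEF2 (2.03), AP-1 (1.17), ROR (1.17), HNF4 (1.47) and TEAD (1.95) rose from below 1. CTCF was at 54.9, nuclear factor I 42.004, CREB 3.12, the neurogenic E-box 4.19, ZIC 6.79, SOX 0.985 and EBF 2.03. NRF1 was at 1.42, YY1 1.76, NFY 1.96, GATA 0.9201 and T-box 0.808. Of 117 motif values from both libraries 24 moved by less than 1 SD and 87 by more, and 6 changed side among motifs over 1.5 or equally far below 1 in both libraries (LIM homeobox under 2 settings, ETS, NRF1, YY1 and NFY); leaving out a replicate of 2 always stays within 1 SD of their mean and so tests nothing here.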

Other observations

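The comparisons here were chosen after the data had been seen. Between the libraries, promoters of the cell-type lists did not move together once they were set against promoters of the same signal and GC content. Granule cell precursor and cell cycle genes, such as Mycn and Pcna, had a median log2 ratio of replicate 2 to replicate 1 of 1.01 against 0.74 in matched random lists (percentile 99.98). Sonic hedgehog pathway genes, which share 7 members with that list, had 0.90 against 0.63 (percentile 99.4), and Bergmann glia and astrocyte genes 0.77 against 0.55 (97.6). Differentiating granule cell genes had 0.79 against 0.76 (68.4) and Purkinje cell genes 0.54 against 0.67 (11.3). GABAergic interneuron genes, such as Gad1, Slc32a1 and Pax2, stood at 0.17 against 0.50 (0.660). Outside promoters, peaks around the GABAergic genes (0.47 against 0.49, percentile 40.5), the hedgehog genes (53.4) and the Bergmann glia genes (48) did not stand apart. Shared peaks outside promoters around the precursor genes went the other way, with 0.37 against 0.58 in peaks matched on signal and GC content, at percentile 0 of 1000 random sets. The promoters and the distal peaks of the same list thus gave opposite orders, and which of the libraries is closer to the tissue cannot be read from either.

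Shared peaks outside promoters had a lower ratio of replicate 2 to replicate 1 signal where CpG dinucleotides were dense. In the decile of peaks with most CpG, with a median of 5.74 per 100 bp, the median log2 ratio was 0.30, against 0.55 in the middle decile with 1.35 per 100 bp. By GC content the median log2 ratio was 0.38 in the highest decile, with 63.6% GC. It was 0.56 in the decile at 51.8% and 0.47 in the lowest decile, at 42.6%. Forebrain genes had 4.17 CpG per 100 bp in these peaks, activity-dependent genes 4.17 and midbrain-hindbrain genes 3.68, while receptor genes had 1.13. Matched on signal and CpG, forebrain, midbrain-hindbrain, precursor and differentiating granule cell peaks stood at percentile 0, activity-dependent peaks at 2.80 and receptor peaks at 89.5.

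A peak in an intron of Mid1, at chrX:169998241-169998400, was the second strongest of replicate 2, with a signal of 61.6, and had 26.1 in replicate 1. Mid1 encodes a microtubule-associated ubiquitin ligase and lies across the pseudoautosomal boundary in laboratory mice.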
